A study of Mus musculus with 2 samples.

How the data were processed

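Single-cell RNA profiles were taken from tumours that grew on the back of nude mice after injection of mouse preSC cells that were either wild type (WT) or knocked out (KO) for Crebbp, per the series' design text. There was 1 library per group, and the sources used here do not say how many tumours or animals each library holds. Tumours were minced, digested with collagenase, elastase and DNase, treated to lyse red blood cells, filtered and depleted of dead cells, and libraries were made with the 10x Genomics 3' v3.1 kit, per the labels' protocols. These steps can alter cell shares and can induce stress genes.

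The deposited values were UMI counts per gene and barcode, made by the authors with Cell Ranger against the mm10 build, per the submitters' processing notes. Those notes give Cell Ranger version 6.0, while the matrix headers give 5.0.0, and the 2 sources were not reconciled here. No normalization had been applied to the counts, which were whole numbers, and the smallest total of a deposited barcode was 500 UMIs in both libraries. The annotation release used for counting was not given in the sources used here. Gene positions were taken from the GENCODE M21 annotation of GRCm38, to which 30934 of the 31053 gene identifiers (99.6%) were matched. Older symbols of list members were found through synonyms in a RefSeq gene table (Cyr61, Ctgf and Ero1l), and Mx2 had no match.

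The work was done in python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9. Barcodes were kept with 500 or more genes, 1000 or more UMIs and under 15% mitochondrial UMIs, which left 16116 WT and 15789 KO barcodes. Doublets were called per library with Scrublet at its automatic threshold. The threshold was 0.459 in the WT library, where 367 barcodes (2.28%) were removed, and 0.309 in the KO library, where 1554 (9.84%) were removed. The kept 15749 WT and 14235 KO cells were clustered together without integration by the Leiden method at resolution 1, from 30 principal components of 2000 variable genes, with 15 neighbours. Of the 24 clusters, 22 were given a class from marker genes listed before the data were examined, with 3 or more detected markers required. The details of the naming rule were settled with the clusters in view. A cluster with high neuroendocrine genes beside the markers of another class stayed unnamed, which applied to 2 clusters. Classes are written as "-like", since the names were rebuilt here and no annotation of cells by the authors was used.

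UMIs were summed over the cells of a class in each library and divided by the total UMIs of that class and scaled to CPM. Intervals of sums are exact 95% Poisson intervals, intervals of shares are exact Clopper-Pearson intervals, and intervals of log2 ratios of KO over WT are exact conditional binomial intervals. All of them cover counting error only. The interval of the immediate early median in host immune classes came instead from resampling the list's genes, and leaves counting error out. A share of 0 is given with the share that the floor of 3 counts would make. A sum under 3 counts entered ratios at a floor of 3, and "at least" is written only where the sum was 0. With 1 library per group, no test between groups was run and no p-value was computed. A gene list was described by the median log2 ratio of its members with 30 or more UMIs over both libraries. That median was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, and a list was said to stand apart under the 5th or over the 95th percentile. By this rule 3.7 of 37 lists of unrelated genes would stand apart by chance. Shares of cells with a UMI of a cycling gene were compared after each cell was thinned to 2000 UMIs, with shallower cells left out.

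The 37 lists and the rule for naming genes were written before the data were examined. Genes needed 100 or more UMIs over both libraries and 20 CPM or more in at least 1 of them. They were ranked by the interval bound nearest 0, and the 12 highest and 12 lowest were named. Mitochondrially encoded, ribosomal protein, haemoglobin and predicted genes were left out of that ranking, as were genes over 10 times higher in another class, which may come from free RNA. Crebbp, its paralogue Ep300 and, of each list that stood apart, the 4 members with the most UMIs and the 2 with the largest difference in the list's direction were also named. The text gives examples of these, and some of them are not reported here. Genes named outside the rule are marked as chosen after their values were seen.

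The alternatives were 14 planned settings for cell filters, doublets, clustering, scaling, weighting of cells, thinning and gene filters. A further 4 settings were added after seeing the data. They counted the haemoglobin-led cluster as neuroendocrine-like, left out WT clusters 6 and 14, left out WT clusters 3 and 5, or left out genes over 10 times higher in a host class.

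The scripts were tested on simulated data, with 200 of 17339 genes changed by known folds. Both libraries were drawn as Poisson counts from 1 profile pooled over the real sums. The intervals assume such counts, so this checks the scripts, not the spread between tumours or the shared regulation of list members. The 95% intervals held the true ratio for 94% of genes raised 2-fold, 96% of genes lowered to 0.5 of their level, 94% of genes raised 1.5-fold, 92% of genes raised 4-fold and 95.6% of unchanged genes. Of 200 lists of unchanged genes 9.5% stood apart, and of 50 lists of 20 genes raised 2-fold 100% did.

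Gene lists in host classes were planned only for classes with 100 or more cells in each library. No class reached this in the main analysis, so those comparisons gave no value. The position of the deleted part of Crebbp was not given in the sources used here.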

Results

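Single-cell RNA-seq was performed on tumours grown from mouse preSC cells, wild type (WT) or knocked out (KO) for Crebbp, after injection on the back of nude mice. Crebbp encodes a histone acetyltransferase and transcriptional coactivator that is inactivated in a share of small cell lung cancers. There was 1 library per genotype, with no replicates, so all values describe the libraries. Their intervals, other than those of medians over genes, cover counting error only. The WT library held 18559 barcodes with a median of 4023 UMIs and 2094 genes, and the KO library held 16282 with a median of 5996 UMIs and 2569 genes. After filtering, 15749 WT and 14235 KO cells were kept and formed 24 clusters. Neuroendocrine-like tumour cells made up 12764 of the WT cells, with a median of 4863 UMIs, and 13017 of the KO cells, with a median of 6046 UMIs.

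Crebbp transcripts were lower in the KO tumour cells but were still detected. The gene was at 121.5 [119, 124] CPM in WT and 72.7 [70.9, 74.5] CPM in KO neuroendocrine-like cells (log2 ratio -0.74 [-0.79, -0.70]), so the KO cells kept 59.8% of the WT level. Across clusters of these cells, Crebbp ranged from 78.7 to 139 CPM in WT and from 53.6 to 89.9 CPM in KO. Host cells, which carry an intact gene, had 105 [99.0, 112] CPM in the WT and 107 [85.4, 132] CPM in the KO library (log2 ratio 0.02 [-0.32, 0.34]). The 3' tag reads the end of the transcript, which may lie outside the deleted part of the gene. Of the genes on either side, looked at for their position, Adcy9 was also lower in KO tumour cells (104.5 and 67.7 CPM) and Trap1 was not (28.4 and 31.3 CPM), so the difference was not confined to Crebbp. The paralogous acetyltransferase gene Ep300 was slightly higher in the KO tumour cells, at 69.3 against 59.8 CPM (log2 ratio 0.21 [0.16, 0.27]).

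Tumour cells dominated both libraries, and cells of the host were far scarcer in the KO library. Immune, stromal and vascular cells were found in both, with few in the KO library. T or NK cells were the largest host class in WT. In KO they (47 cells) and macrophages or monocytes (44 cells) were too close to rank. Of the classes seen in both libraries, fibroblasts showed the widest gap. Neuroendocrine-like cells were 81.0% [80.4, 81.7] of WT and 91.4% [91.0, 91.9] of KO cells. Host classes together were 18.7% [18.1, 19.3] of WT cells (2946) and 1.23% [1.05, 1.42] of KO cells (175), a 15.2-fold gap. T or NK cells were 6.86% against 0.330% (20.8-fold), macrophages or monocytes 3.84% against 0.309% (12.4-fold), and B or plasma cells 2.78% against 0.267% (10.4-fold). Fibroblasts were 2.60% against 0.0421% (61.8-fold), with only 6 cells in the KO library. Endothelial cells were 1.05% against 0.112% (9.38-fold), pericytes or smooth muscle cells 1.03% against 0.119% (8.61-fold) and keratinocytes 0.197% against 0.0492% (4.003-fold). Lymphatic endothelial cells were 0.343% of WT cells and 0 of 14235 KO cells, which at the floor of 3 counts allows a share of up to 0.0211%. Among host cells alone, T or NK cells were 36.7% in WT and 26.9% in KO, macrophages 20.5% and 25.1%, B or plasma cells 14.9% and 21.7%, and fibroblasts 13.9% and 3.43%. Unnamed clusters held 0.248% of WT and 7.33% of KO cells. Of these KO cells 1007 lay in a cluster led by haemoglobin genes beside neuroendocrine genes. Counting that cluster as neuroendocrine-like gave a KO share of 98.5%. With other cell filters, with doublets kept or with other clusterings, the KO share was 93.4% to 98.7%, above the main interval. The main KO share of neuroendocrine-like cells thus depends on the naming rule. With a stricter cell filter the host share was 9.82% of WT and 0.705% of KO cells, and with almost no filter the KO share was 2.36%. Digestion and dead cell removal can set such shares, and no host class held enough cells in both libraries for its own gene comparison.

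**Figure D1:**
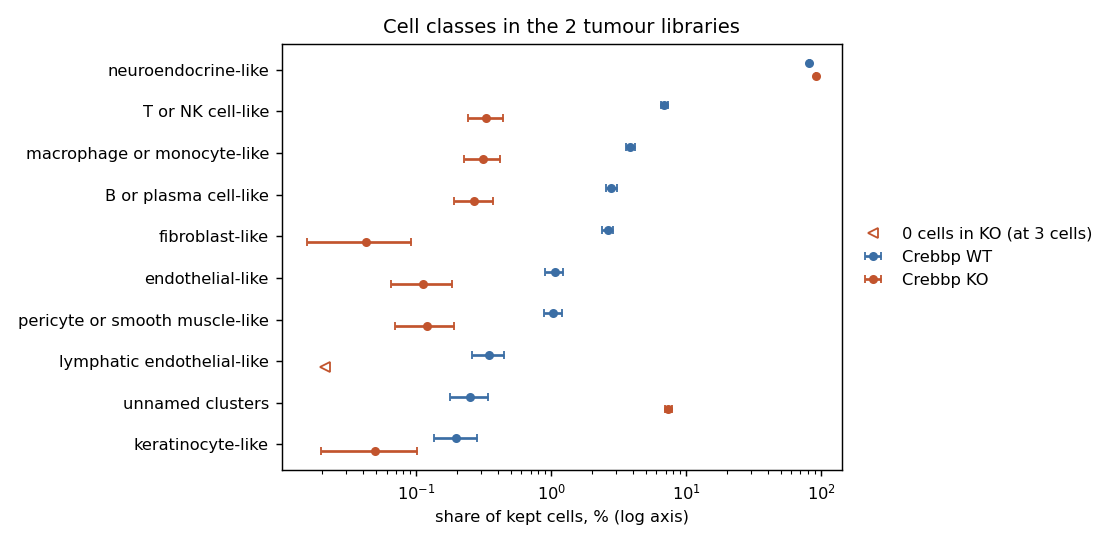
Share of each cell class among the kept cells of the Crebbp WT and Crebbp KO libraries, on a log scale with exact 95% intervals that cover counting error only. Host classes sit lower in the KO library (1.23% of cells together) than in the WT library (18.7%), and a class with no cell is drawn at a floor of 3 cells.

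The neuroendocrine-like cells of the WT and KO libraries differed widely and lay almost wholly in different clusters. WT cells lay in clusters 0, 1, 2, 3, 5, 6, 8 and 14 and KO cells in clusters 11, 12, 18, 20, 21 and 22, with 3 KO cells in the WT clusters and no more than 63 WT cells in any KO cluster. Among the 12 genes with the largest difference toward KO were Isl1, the eye and ear regulator Eya1, the zinc finger genes Bcl11a, Zfhx4 and Bnc2, the forkhead gene Foxr2 and the homeobox gene Dlx6. Among the 12 with the largest difference toward WT were Anxa1, the claudin gene Cldn7, Wfdc2, the immediate early gene Egr3 and the growth factor gene Hgf. Of 17339 genes measured in these cells, the median log2 ratio of KO over WT was -0.09.

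Eya1 was at 0.0640 CPM (5 UMIs) in WT and 124 CPM in KO (log2 ratio 10.92 [9.70, 12.54]). Bcl11a stood at 0.0767 and 119 CPM (log2 ratio 10.60), Zfhx4 at 0.0895 and 110.1 CPM (10.26), Foxr2 at 0.102 and 54.7 CPM (9.06) and Bnc2 at 40.9 CPM in KO with 6 UMIs in WT (9.06). Isl1, which encodes a LIM homeodomain factor of neurons and endocrine cells, had 1 UMI in WT and 93.1 CPM in KO. Single UMIs in WT were also the whole signal of Tspan6 (38.8 CPM in KO) and Fign (30.6 CPM), and Twist1, a regulator of mesenchymal programs, had 2 UMIs in WT and 25.7 CPM in KO. No WT molecule was seen of Dlx6 (24.7 CPM in KO, at least 645-fold), its antisense transcript Dlx6os1 (28.7 CPM, at least 748-fold) or the G protein gene Gnai1 (26.4 CPM, at least 688-fold). In the other direction, Anxa1 was at 172 CPM in WT and 0.0690 CPM in KO (log2 ratio -11.29 [-12.73, -10.16]) and Cldn7 at 342 and 0.241 CPM (-10.47 [-11.16, -9.85]). Wfdc2, a secreted protease inhibitor gene, was at 1536 and 1.81 CPM (-9.73), the hair keratin-associated gene Krtap17-1 at 425 and 0.264 CPM (-10.65) and Egr3 at 349 and 0.368 CPM (-9.89). R3hdml (233 CPM in WT, 0.207 in KO), the imprinted gene Mest (117 and 0.172), the adhesion gene Chl1 (98.3 and 0.0805), Rab25 (85.2 and 0.103) and Hgf (83.0 and 0.0690) were likewise almost confined to WT. Gria3, a glutamate receptor gene, was at 57.4 CPM and Cdcp1 at 37.4 CPM in WT, each with 3 UMIs in KO.

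**Figure D2:**
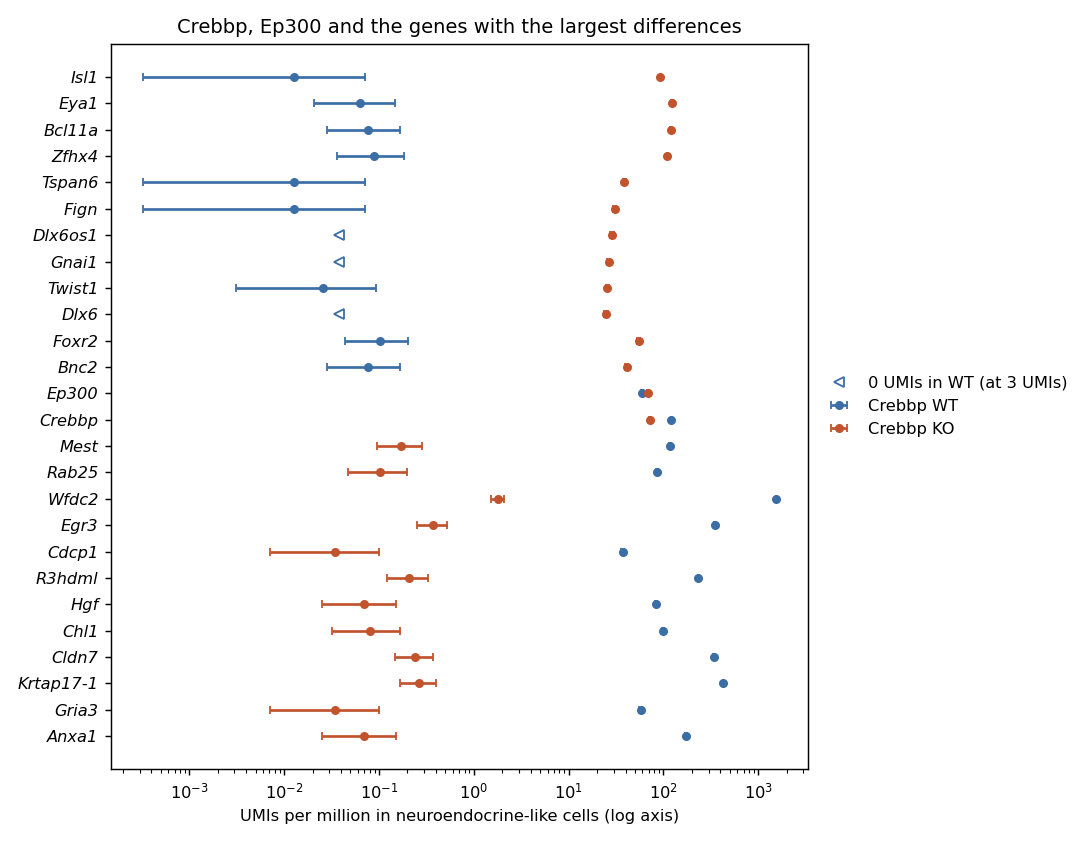
CPM of Crebbp, Ep300 and the genes with the largest differences in neuroendocrine-like cells of the Crebbp WT and Crebbp KO libraries, with 95% counting intervals. The KO library sits above the WT library for genes such as Eya1 and below it for genes such as Anxa1, and a gene with no UMI is drawn at the 3-count floor.

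Epithelial adhesion genes were lower in the KO tumour cells, and so were most secretory neuroendocrine genes. Krt8, Krt18, Krt7, Epcam and Cldn7, all abundant in WT cells, were lower in KO cells. Among secretory neuroendocrine genes, the calcitonin gene and the monoamine transporter gene Slc18a1 were lower, while Ddc, Syt1 and Uchl1 were moderately higher. Neuroendocrine and neural transcription factors as a group did not shift. The 35 epithelial genes had a median log2 ratio of -3.11, below every random list, and 31 of them were at least 2-fold lower. Krt8 was at 1995 CPM in WT and 14.4 CPM in KO (139-fold), Epcam at 1723 and 38.3 (44.9-fold), Krt18 at 2084 and 133 (15.6-fold) and Krt7 at 1340 and 242 (5.54-fold). Cldn6 was at 29.4 CPM in WT and had no UMI in KO, at least 853-fold lower. The neuroendocrine secretory list had a median of -0.75, also below every random list, with 19 of 26 members lower, 10 of them at least 2-fold, and 1 at least 2-fold higher. Calca was at 3259 CPM in WT and 637 CPM in KO (5.11-fold lower) and Slc18a1 at 102 and 4.24 CPM (24.1-fold lower). By contrast, Ddc was at 809 and 1384 CPM, Syt1 at 488 and 753 CPM and Uchl1 at 454 and 725 CPM. The transcription factor list had a median of -0.01 (percentile 64.4), with 7 of 23 members at least 2-fold higher and 3 lower. Genes picked from it after their values were seen were Nfib, at 157 CPM in WT and 516 CPM in KO, and Sox2, with a log2 ratio of 4.68. The mesenchymal list had a median of -0.21 (percentile 28.9), with 7 genes at least 2-fold higher and 11 lower. Without genes far higher in a host class its median was 0.52 and it stood apart on the higher side, while it stood apart on the lower side with a stricter cell filter (-0.59), at a coarser clustering (-0.55), with libraries clustered on their own (-0.88) and without WT clusters 6 and 14 (-0.49).

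Immediate early genes and targets of cAMP signalling were much lower in the KO library. The AP-1 genes Jun, Fos and Jund and the early growth response genes Egr2 and Egr3 were among the most abundant or most different of them. CREB, the factor that gave Crebbp its name, drives many of the cAMP targets. Immediate early genes are also induced when tissue is digested, and they were lower in the KO host immune cells too. In neuroendocrine-like cells all 29 immediate early genes were lower in KO, with a median log2 ratio of -4.00. Jun was at 4699 CPM in WT and 431 CPM in KO (10.9-fold), Fos at 2750 and 56.8 CPM (48.4-fold), Jund at 1788 and 300.5 CPM, Hsp90aa1 at 1642 and 856 CPM and Egr2 at 67.3 and 0.793 CPM. The 17 cAMP and CREB targets had a median of -2.25, and -1.39 without the members shared with the immediate early list, against -1.87 and -0.74 in host immune cells without tumour transcripts. Nr4a1 was 28.0-fold lower (146 and 5.23 CPM), the G protein regulator gene Rgs2 13.1-fold (271 and 20.6 CPM), the prohormone convertase gene Pcsk1 8.84-fold (487 and 55.1 CPM) and Pde4d less so (1056 and 433 CPM). Host immune cells without tumour transcripts (1310 WT and 66 KO cells) are, here and below, those with no UMI of 7 tumour genes. In WT T or NK cells their median was 1349 UMIs, against 5097 in cells with 5 or more such UMIs. At that depth some tumour RNA may remain in them. In these host immune cells the immediate early list had a median of -1.94 [-2.41, -1.68], with 27 of 27 genes lower. The KO cells among them were only 35 T or NK, 23 macrophage or monocyte and 8 B or plasma cells.

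Antigen presentation and interferon response genes were lower in the KO tumour cells. The classical class I genes H2-D1 and H2-K1 were lower, while the chaperone gene Calr was level. Interferon-induced genes, chemokines and inflammatory genes were lower as groups, although many members were far higher in host cells. The MHC class I list had a median log2 ratio of -2.40, below every random list. H2-D1 was at 470.1 CPM in WT and 69.5 CPM in KO (6.76-fold), H2-K1 at 281 and 104.5 CPM (2.69-fold), the proteasome activator gene Psme1 at 329.5 and 265 CPM, Pdia3 at 347 and 245 CPM and Calr at 287 and 288 CPM. The interferon list had a median of -1.96, with 21 of 28 genes at least 2-fold lower, among them Rsad2 (31.7 and 12.3 CPM), while Ifi35 (58.5 and 39.5 CPM) and Stat2 (17.7 and 10.99 CPM) were less so. Without genes over 10 times higher in a host class, class I was at -1.75 (20 of 24 genes left) and interferon at -1.20 (only 7 of 28 left). Such genes, which may come from free RNA, were 11 of 20 chemokine and cytokine genes and 6 of 10 inflammatory macrophage genes. Host cells were 18.7% of WT but 1.23% of KO cells, so free host RNA may add to these differences, which was not tested. In host immune cells without tumour transcripts, class I was at -0.68, interferon at -0.72, MHC class II at -1.23 and the inflammatory macrophage list at -1.30. Chemokines and cytokines had a median of -1.95, with Vegfc 8.16-fold lower (68.8 and 8.44 CPM) and Pdgfa at 63.5 and 18.6 CPM. Mif, which encodes a cytokine of many tumour cells, was 4.56-fold higher (576 and 2625 CPM). The inflammatory macrophage list, read here in tumour cells, had a median of -2.30, with the NF-kB regulator gene Nfkbiz 6.89-fold lower (78.2 and 11.4 CPM) and Sod2 at 261 and 158 CPM. MHC class II genes had a median of -2.54, but 9 of 10 may be free RNA and the leading member, Cd74, reached only 3.27 CPM in WT and 0.621 CPM in KO.

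**Figure D3:**
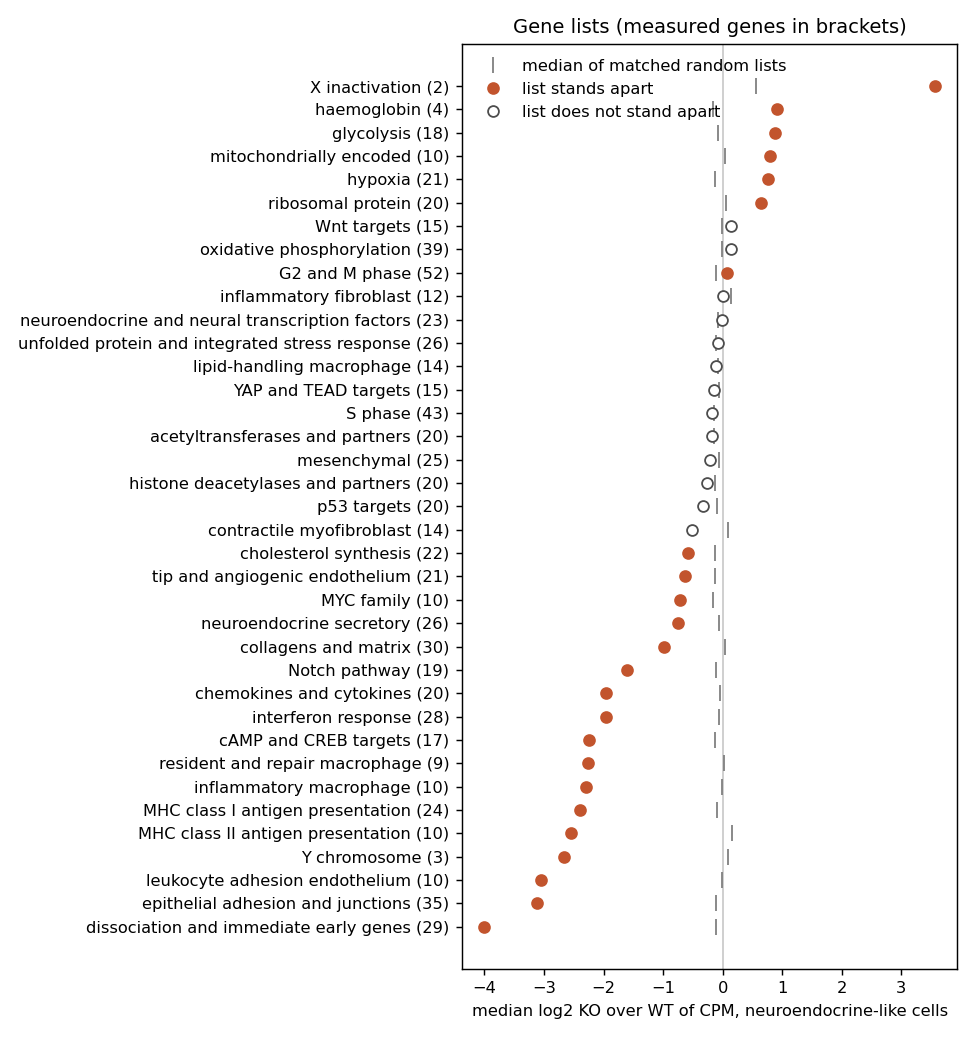
Median log2 ratio of KO over WT for 37 gene lists in neuroendocrine-like cells, with lists that stood apart from matched random lists marked. Immediate early genes (-4.00) lie furthest to the lower side.

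Metabolic genes were higher in the KO tumour cells, and several of these differences were also seen in host immune cells. Glycolytic enzymes and targets of the hypoxia response were higher together, with Hk2 and P4ha2 scarce in WT. Ribosomal protein and mitochondrially encoded genes were higher as well, while oxidative phosphorylation genes of the nucleus stayed level. Cholesterol synthesis genes were lower. The glycolysis list had a median log2 ratio of 0.87, above every random list, with 16 of 18 genes higher. Pgk1 was 5.61-fold higher (142 and 798 CPM), Aldoa 4.18-fold (204 and 854 CPM), Gapdh 2.47-fold (1281 and 3160 CPM) and Hk2, the inducible hexokinase gene, 17.1-fold (2.05 and 35.0 CPM). Hypoxia genes had a median of 0.76, with P4ha2 at 0.819 CPM in WT and 87.0 CPM in KO (106-fold), Pfkfb3 at 1.69 and 25.4 CPM (15.1-fold), Bnip3 at 40.3 and 146 CPM (3.61-fold) and Bnip3l lower at 233 and 154 CPM. The mitochondrially encoded list had a median of 0.79 (percentile 99.8), led by mt-Nd1 at 507 and 1519 CPM, and the ribosomal list 0.64 (percentile 99.9), led by Rps12 at 588 and 2202 CPM. Oxidative phosphorylation was at 0.14 (percentile 84.0). Cholesterol synthesis had a median of -0.59 (percentile 0.52), with Insig1 3.90-fold lower (102 and 26.3 CPM). In host immune cells without tumour transcripts, medians were 0.58 for glycolysis, 0.43 for hypoxia, 0.64 for mitochondrially encoded genes and -0.68 for cholesterol synthesis, against -0.07 for ribosomal protein genes. These host medians rest on 66 KO cells and were given no interval and no place among random lists.

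Notch and MYC family genes were lower in the KO tumour cells. Most members of the Notch list were lower, among them the ligand genes Dll3 and Dll4, while the pathway's transcription factor gene Rbpj was slightly higher. Myc and Mycn were both low in KO, and their partner gene Max was not. The Notch list had a median log2 ratio of -1.60, with 15 of 19 members lower. Among them were Dll3 at 61.0 CPM in WT and 20.1 CPM in KO (3.03-fold), Dll4 at 16.4 and 0.828 CPM (19.8-fold) and Maml2 at 53.9 and 15.1 CPM, while Rbpj was at 74.7 and 87.6 CPM. The MYC family list had a median of -0.72 (percentile 2.49), and it stood apart no longer when cells were thinned to 2000 UMIs (percentile 5.56). Myc was at 20.4 and 2.64 CPM (7.70-fold), Mycn at 9.29 and 1.97 CPM (4.72-fold), Mxd4 at 74.2 and 31.9 CPM and Max at 41.0 and 52.7 CPM. WT cluster 6 supplied 304 of the 726 WT UMIs of Mycn, and in the other WT tumour clusters the gene was at 5.57 CPM. Without WT clusters 6 and 14 its log2 ratio was -1.54.

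Lists named for stromal cells were mostly lower in KO, and many of their members were far higher in host cells. Some members were expressed by the tumour cells themselves. Thbs1, Col8a1, Vwf and the placental growth factor gene Pgf were abundant in WT tumour cells and lower in KO. The leukocyte adhesion list had a median log2 ratio of -3.04, against -1.57 in host immune cells without tumour transcripts, with Vwf 11.6-fold lower (408.5 and 35.2 CPM). Collagens and matrix were at -0.99, with Thbs1 at 260 CPM in WT and 0.862 CPM in KO (301-fold) and Col8a1 at 741 and 226 CPM, but 26 of its 30 members were far higher in a host class and without them this list stood apart no longer (-0.61, percentile 14.9). Tip endothelium was at -0.63 (percentile 3.76), with 16 of 21 members far higher in a host class and Pgf at 95.5 and 23.1 CPM (4.13-fold). The resident macrophage list split, with a median of -2.25 set by scarce complement genes, while the selenoprotein gene Selenop (1.496 and 60.7 CPM, 40.6-fold) and the transcription factor gene Maf (0.524 and 24.998 CPM, 47.7-fold) were higher in KO. Its median turned to 5.34 once only genes with 300 or more UMIs, or none far higher in host classes, were kept, and the list stood apart no longer with cells thinned (-1.09) or with no gene filter (-0.15). The contractile list was at -0.51 (percentile 9.28), the inflammatory fibroblast list at 0.00 (percentile 40.8) and the lipid-handling macrophage list at -0.11 (percentile 46.1). Contractile genes stood apart with a stricter cell filter (-0.67). Y-linked genes were scarce in both libraries, with a median of -2.66 (percentile 2.58) and Ddx3y at 4.31 CPM in WT and 1.98 CPM in KO. All 3 were far higher in host cells (Ddx3y at 63.9 CPM in WT T or NK cells). Xist, the RNA of X inactivation, was at 0.217 and 2.53 CPM, and the 2 genes of that list had a median of 3.56 (percentile 95.1), which stood apart no longer under several settings, down to 3.36 with libraries clustered on their own. Haemoglobin genes had a median of 0.91 (percentile 96.4), with Hbb-bs at 22.2 and 32.7 CPM, and turned negative with a stricter cell filter (-0.14) or libraries clustered on their own (-0.65).

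The remaining lists did not stand apart in the main analysis. Wnt targets were at 0.15 (percentile 65.1), with 5 genes at least 2-fold higher and 5 lower, and stood apart at -1.16 (percentile 2.53) when only genes with 300 or more UMIs were kept. YAP and TEAD targets were at -0.14 (percentile 40.6), and stood apart at -1.27 after thinning, at -1.28 with 300 or more UMIs and at -0.71 without genes far higher in host classes. Acetyltransferases and partners were at -0.18 (percentile 42.4), histone deacetylases at -0.26 (percentile 23.4), p53 targets at -0.34 (percentile 11.9) and unfolded protein response genes at -0.07 (percentile 59.2).

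Tumour cells of both genotypes were cycling, and the markers did not agree on which library cycled more. Mki67, a marker of all phases but G0, was found in slightly more KO cells, Top2a in about as many at the main depth, and the replication clamp gene Pcna in fewer. With each cell thinned to 2000 UMIs, Mki67 was seen in 22.2% [21.5, 22.98] of WT and 25.3% [24.5, 26.0] of KO cells, Top2a in 29.1% and 28.1%, and Pcna in 15.6% and 8.65%. Shallower cells were left out, 1020 in WT and 274 in KO. Without thinning the shares were 35.6% and 40.8% for Mki67, 41.7% and 38.4% for Top2a and 33.5% and 25.3% for Pcna. After thinning to 2000 UMIs, Mki67 was in 4.51% of WT fibroblasts but in 20.2% [14.7, 26.7] of 188 WT B or plasma cells. That thinning left out 250 shallower WT B or plasma cells. Of all 438, 182 held 5 or more UMIs of 7 tumour genes, at a median of 5410.5 UMIs. Tumour RNA may thus add to the B or plasma share, which was not tested. These host classes therefore set no clean background. At 4000 UMIs Mki67 was in 38.3% of WT and 38.0% of KO cells, and at 1000 UMIs in 13.3% and 16.4%. Top2a at 4000 UMIs was in 45.2% of WT and 37.5% of KO cells, and Pcna in 29.1% and 17.5%. The order turned with libraries clustered on their own (26.6% of WT and 23.9% of KO cells) and without WT clusters 3 and 5 (31.5% of WT cells). Genes of G2 and M phase had a median log2 ratio of 0.07 (percentile 96.0), with Hmgb2 at 966 and 1195 CPM and Ube2c at 383 and 591 CPM, but Cenpf lower at 454 and 315 CPM. This median turned negative without WT clusters 3 and 5 (-0.58) or with libraries clustered on their own (-0.17), and the list stood apart no longer without a cell filter, with doublets kept, at a finer clustering or with the haemoglobin-led cluster counted. S phase genes were at -0.17 (percentile 39.6).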

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

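No test in this part was chosen after the result was seen. A pair of clusters left out of the main comparisons held more cells than a count of 0 allows, which is why they are given here. Cluster 7, with neutrophil genes beside neuroendocrine genes, held 0.146041% of the kept cells of the WT library (23 cells) and 0.252898% of those of the KO library (36 cells). Cluster 19, led by haemoglobin genes beside neuroendocrine genes, held 0.101594% of WT cells (16) and 7.07411% of KO cells (1007). Haemoglobin made up 33.9% of the UMIs of its WT cells and 0.883% of those of its KO cells, against 0.00351% and 0.00609% in neuroendocrine-like cells. No explanation was tested for these cells, and no biological one was weighed.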

How the results depend on the processing

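Of the 18 settings, 4 were chosen after the results were seen: the haemoglobin-led cluster counted as neuroendocrine-like, the settings without WT clusters 6 and 14 or without WT clusters 3 and 5, and the one without genes over 10 times higher in a host class. The cause was not tested for any difference below. Of 584 list medians 554 either stood apart on the same side as in the main analysis or stood apart in neither. This held under every alternative for 18 of the 24 lists that stood apart and for 9 of the other 13. A list that stood apart in neither could change direction, as acetyltransferases and partners did (-0.21 to 0.005). Of 1950 values of named genes 1382 were within the main interval and 10 reversed a direction whose main interval excluded 0. The other 558 lay outside the main interval. Of 112 shares of single host classes 85 stayed within the main interval, and of 44 Top2a and Pcna shares 22 did. Gene lists in host classes have no value to compare, since no class held 100 cells in both libraries in the main analysis, and 1 class did only with no filter beyond 200 genes, where its lists were not run. Also, a few short lists lacked a value under some settings. Median-of-ratios factors moved every log2 ratio by 0.125 and totals without the most abundant genes by 0.187.

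With the stricter cell filter, neuroendocrine-like cells were 88.9% of WT and 98.7% of KO cells, host classes 9.82% and 0.705%, and Mki67 was seen in 21.1% and 24.2%. The median was -0.59 for the mesenchymal list, -0.67 for the contractile list and -0.14 for haemoglobin, and Hbb-bs was at -0.50. With no filter beyond 200 genes, the neuroendocrine-like shares were 74.7% and 96.4%, host shares 24.0% and 2.36%, Mki67 in KO 24.2% and the G2 and M list 0.0172. With doublets kept, these were 79.6% and 97.0%, 20.3% and 1.47%, with G2 and M at 0.0168 and X inactivation at 3.42. At Leiden resolution 0.5 they were 77.8% and 97.4%, 22.1% and 1.48%, with mesenchymal at -0.55 and X inactivation at 3.54. At resolution 2 the neuroendocrine-like shares were 81.7% and 97.0%, the WT host share 17.4%, Mki67 in KO 24.4% and G2 and M 0.0112.

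With each library clustered on its own, neuroendocrine-like cells were 64.3% and 93.4% (with 2894 WT and 729 KO cells unnamed), host classes 17.3% and 1.48%, and Mki67 was in 26.6% and 23.9%. There the mesenchymal list was at -0.88, G2 and M at -0.17, X inactivation at 3.36, haemoglobin at -0.65, Hbb-bs at -0.95, Hba-a1 at -0.23 and Hba-a2 at -0.36. After thinning to 1000 UMIs Mki67 was in 13.3% of WT and 16.4% of KO cells, and after thinning to 4000 UMIs in 38.3% and 38.0%. Lists in cells thinned to 2000 UMIs gave YAP and TEAD -1.27, MYC family -0.60 and resident macrophage -1.09. Genes with 300 or more UMIs gave YAP and TEAD -1.28, Wnt -1.16 and resident macrophage 5.34, and a filter of 1 UMI gave resident macrophage -0.15.

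Crebbp was at -0.62 with median-of-ratios factors, -0.55 with totals without the most abundant genes and -0.79 as the mean over cells. Median-of-ratios factors put X inactivation at 3.69 and Top2a at 0.0486, and reduced totals put Top2a at 0.11, Mga at 0.0395 and Insr at 0.0271. Counting the haemoglobin-led cluster gave a KO share of 98.5%, Mki67 in KO 24.1%, G2 and M 0.00907 and X inactivation 3.54. Without WT clusters 6 and 14, mesenchymal was at -0.49 and X inactivation at 3.56. Without WT clusters 3 and 5, Mki67 was in 31.5% of WT cells, G2 and M was at -0.58, Hmgb2 at -0.14 and Ube2c at -0.12. Without genes over 10 times higher in a host class, mesenchymal was at 0.52, YAP and TEAD at -0.71, collagens and matrix at -0.61 and resident macrophage at 5.34.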

Other observations

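A few WT neuroendocrine-like cells formed clusters of their own that differed from the other WT neuroendocrine-like cells. They are described here because their genes were picked after the clusters were seen. The tests on extra copies of a region, on a few strongly changed genes and on KO cells in the WT library were chosen after the results were seen, and the test on handling was given an added condition after its first value was seen. The other tests were written before. WT cluster 6 held 577 WT cells with a median of 6390 UMIs. Its cells had Mycn at 79.2 CPM against 5.57 CPM in the other WT neuroendocrine-like cells, the neighbouring genes Ddx1 at 666 against 111 CPM and Nbas at 518 against 64.5 CPM, and the axon guidance receptor gene Dcc at 436 against 4.41 CPM. They were lower than other WT cells for the epithelial list (median log2 ratio -2.96), immediate early genes (-2.88), interferon genes (-1.80) and MHC class I (-1.31), and higher for S phase (0.63) and G2 and M phase genes (0.64). Set against separate random sets of the other WT tumour cells, differences of cluster 6 and of KO cells went together across 11454 genes (Pearson r 0.64), and 655 of 850 genes at least 4-fold lower in KO were at least 2-fold lower in cluster 6, as were 15.1% of all genes. WT cluster 14 held 454 WT cells with a median of 1672.5 UMIs, with Pvt1 at 1385 against 40.8 CPM, its neighbour Fam84b at 337 against 23.5 CPM, Myc at 70.5 CPM and the neuronal gene Rtn1 at 540 against 6.58 CPM. Pvt1 was detected in 22.03% of its cells, Fam84b in 19.4% and Myc in 9.47%, and the cluster also stood apart for Y-linked (3.69), resident macrophage (1.72) and MHC class II genes (1.41). Its Y-linked gene Eif2s3y was at 29.8 CPM, against 21.1 CPM in WT B or plasma cells and 44.6 CPM in WT T or NK cells. Uty was at 11.6 CPM, against 1.16 CPM in all WT neuroendocrine-like cells. Cluster 14 may thus hold host cells or host RNA beside tumour cells, which was not tested.

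Although the hosts were nude mice, which lack a normal thymus, WT T or NK cells held the T cell receptor gene Trac at 287 CPM. They also held Cd3e at 185 CPM, Cd8a at 129 CPM and Cd4 at 41.6 CPM, beside the NK cell genes Ncr1 at 42.0 CPM and Klrb1c at 30.9 CPM. B or plasma cells of the WT library had Cd79a at 838 CPM and Ighm at 2716 CPM. Tumour transcripts were seen in host cells, where 14.1% of WT T or NK cells and 41.6% of WT B or plasma cells held 5 or more UMIs of 7 tumour genes. Host transcripts in tumour cells were scarce, with Ptprc at 0.307 CPM in WT and 0.126 CPM in KO.

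Immediate early genes were lower in KO tumour cells, and handling or digestion of the tumours could account for it. Their median log2 ratio in host immune classes, where Crebbp was not knocked out, was -2.19 [-2.73, -1.98]. This was past the bound of -1.999, which was set from the -4.00 seen in tumour cells. The classes were weighted equally. The interval came from resampling the list's genes and leaves out counting error in the 129 KO cells. It reached beyond that bound, and under the condition added later, host immune cells without tumour transcripts, the median was -1.94, so handling stays open. WT clusters 3 and 5, of which only cluster 5 stood apart on the higher side for this list (1.10 against other WT tumour cells), did not account for it, since the median was -3.54 without them. A loss of Crebbp as coactivator of CREB was not tested, since genotype and handling cannot be separated with 1 library per genotype.

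The Mycn region was high in WT cluster 6, and extra copies of the region may account for it. All 6 genes from Gm47833 to Nbas were over 2 times higher in that cluster, but the flanking genes on the left had a median of -0.59, outside the range of 0.5 around 0 that was set for them. The 6 genes were chosen for this pattern and RNA holds no copy number, so the question stays open. The rule set for KO tumour cells in the WT library left them undecided. Of 120 genes at least 16-fold higher in KO than in the other WT tumour clusters, cluster 6 had a median of 6.59% of the KO level. Of these genes 67 were under 10% and 19 over 50%. Its Mycn level of 79.2 CPM was far over the 1.97 CPM of KO cells. Chromosome 1 genes of cluster 6 were at -0.05 and chromosome 15 genes at -0.01 (median log2 ratio relative to all genes). The KO clusters lay from -0.48 to -0.39 and from 0.48 to 0.51. These medians were not part of the rule, and they argue against cluster 6 being KO cells. No biological explanation from the design applies, since the cluster lies within the WT library.

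Genes of chromosome 1 were lower in the KO tumour cells (median log2 ratio relative to all genes -0.41 [-0.48, -0.34]) and those of chromosome 15 higher (0.51 [0.43, 0.57]), in all 6 KO clusters. GC content and transcript length did not account for it, since the chromosome 1 median was -0.47 after regression on them. Of the chromosome 1 genes 70.6% lay below the median of all genes, so the difference was spread over many genes. A negative chromosome median already puts most genes there, so this test on a few strongly changed genes adds little to it. The test replaced a first one on windows of 20 genes, of which 29 of 37 lay below and which left the question open. A dosage difference of whole chromosomes was consistent with the 100% of chromosome 15 windows above that median, but less clearly with the 78.4% of chromosome 1 windows below it, since chromosome 9 had 83.3% below at a median of only -0.14, chromosome X was at 0.30 [0.15, 0.42], and RNA does not measure DNA copies. Whether such a difference came with the Crebbp knockout or with the cell clone was not tested.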
